A study of Mus musculus with 8 samples.

How the data were processed

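RNA was sequenced from inguinal white adipose tissue (iWAT) and brown adipose tissue (BAT) of male C57BL/6 mice, aged 16 weeks, with a fat-specific knockout of *Mecp2* (KO) and of floxed controls (WT), per the labels. The mice were fed normal chow and kept at 22 °C. RNA was extracted from each mouse with RNAiso Plus, and equal amounts from 3 mice were pooled into each sample, per the labels' protocols. There were 8 libraries in 4 groups, with 2 libraries per group, and the replicate is the pool. Libraries were made with standard Illumina protocols, and whether the counting used strand is not stated.

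The authors deposited expression values as FPKM, reads scaled by the length of the gene and the depth of the library, in 1 table per group. The unit was taken from the values, since the headers name only the libraries. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq 1.18.0, with no role for each, and the genome build GRCm38. The tables held 42754 Ensembl genes, of which 26300 were above 0 in at least 1 library. Symbols and coordinates were taken from GENCODE M21 (GRCm38) for 42317 of the gene IDs.

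Within a gene, the deposited values of a library are whole multiples of 1 step. The whole reads behind every one of the 26300 genes above 0 were recovered from these steps, with a tolerance of 0.002 for a whole read. The steps gave 9062560 to 11693476 counted reads per library, a ratio of 1.29 between the highest and the lowest. Recovered reads were used for depths, shares of reads and 1 alternative test. The 2 libraries of a group were not copies of each other. Their chi-square per gene, over genes with at least 20 reads, was 7.92 in iWAT WT, 5.82 in iWAT KO, 1.75 in BAT WT and 1.72 in BAT KO, where counting error alone gives about 1.

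A test on counts had been planned before the data were examined, with a written fallback for normalized values. The files held FPKM and no counts, so the fallback was used. Values were transformed to log2(FPKM + 1), without further scaling, and genes with a mean of at least 1 FPKM over the 8 libraries were kept, which left 13347 genes. Limma 3.58.1 in R 4.3.3 was fitted to all 8 libraries with 1 coefficient per group and an intensity trend in the prior variance (limma-trend). This left 4 residual degrees of freedom and 5.33 prior degrees of freedom, 9.33 in all. The contrasts were KO against WT in iWAT, KO against WT in BAT, the difference of these changes between the tissues, and BAT against iWAT in WT. Adjusted p-values are Benjamini-Hochberg values over all genes tested, two-sided, with a threshold of 0.05. The pseudocount of 1 shrinks the fold changes of genes near or below 1 FPKM.

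Before the data were examined, 33 gene lists with 938 members were fixed for adipose metabolism, for MeCP2 and for the other cell types that such tissue can hold. A gene ID was matched to 935 members, and 806 passed the filter. The list of testis and epididymis genes had no measured member, so 32 lists were tested. Each list was tested against all other genes with camera, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. The same test with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were alternatives. With an estimated correlation, camera called 0 lists even between the tissues of the control mice, so a miss by it does not set a list aside. Counts of members are given over all genes tested and adjusted over the list alone.

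The genes named in the text were chosen by a rule fixed before the data were examined. It takes *Mecp2*, the 8 genes that rose and the 8 that fell most in each genotype comparison, up to 4 members of each list described, and *Ucp1*, *Adipoq*, *Lep*, *Pparg*, *Ppargc1a* and *Fasn* in every comparison. It also takes the genes with the smallest adjusted p for the tissue difference, up to 6. The largest changes were taken among genes past the threshold with a mean of at least 1 FPKM in the tissue, both KO libraries beyond both WT libraries, and a symbol that is not a model name. Within a list, 2 members with the smallest adjusted p were taken. A gene named outside this rule is said to have been chosen after its values were seen.

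The test was run on simulated data before it was run on the deposited values. Reads were drawn for the 13347 genes from the means and depths of the real libraries, in 5 simulations with 100 genes changed by a log2 fold of 0.5 and 100 by 1. The list of ribosomal protein genes was also shifted, by 0.4. Camera called it (mean camera adjusted p = 4.4e-39 for iWAT and 1.9e-63 for BAT) and called 0 unshifted lists. Genes were drawn independently, so this did not test correlation within a list. For the iWAT comparison, 20.6% of the smaller and 74.4% of the larger changes were recovered, and 12.5% of the calls were false. For the BAT comparison, these were 24.2%, 73.4% and 3.3%. In fits to the tissue alone they were 3.6%, 59% and 7.7% for iWAT and 0.4%, 10.4% and 1.4% for BAT.

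Alternatives fixed before the data were examined were median-ratio scaling, quantile normalization, no filter, a stricter filter (mean of at least 5 FPKM in the tissue), a pseudocount of 0.1, a fit to the groups compared alone, the replicate number as a block, leaving out each library in turn, leaving out mitochondrially encoded genes, and a fold threshold of 1 on the log2 scale. Limma-voom on the recovered reads, with a mean of at least 10 reads, and scaling of every library on the adipocyte identity list were added after the data were seen. This scaling divides a library by 1 factor, taken from the median of that list. It therefore holds the list's own median near 0 by construction and shifts the other genes of a library together. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.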

Results

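Expression was measured by RNA sequencing in iWAT, a white fat depot in which thermogenic adipocytes can arise, and in BAT, the heat-producing fat, of mice with a fat-specific *Mecp2* knockout and of floxed controls. *Mecp2* encodes a protein that binds methylated DNA. Each of the 8 libraries was a pool of RNA from 3 mice, with 2 pools per group. Counted reads per library were 11567008 and 10657832 in iWAT WT, 11057357 and 11059887 in iWAT KO, 11693476 and 9062560 in BAT WT, and 9425601 and 11360400 in BAT KO. Levels are mean FPKM ± SD (n = 2 pools), changes are log2 differences of FPKM + 1 (KO minus WT) ± SE, and adjusted p-values for genes are from limma. The SD between pools of 3 mice understates the spread between single mice.

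*Mecp2* (ENSMUSG00000031393, chromosome X, 74026592 to 74135363, GRCm38) was at 4.38 and 4.50 FPKM in the BAT WT libraries and at 1.75 and 1.56 FPKM in the BAT KO libraries. In iWAT it was at 6.13 and 6.39 FPKM in the WT libraries and at 5.23 and 6.05 FPKM in the KO libraries. It fell in BAT (-1.04 ± 0.12, 95% confidence interval -1.32 to -0.76, limma adjusted p = 0.00207). The iWAT difference did not pass the threshold (-0.13 ± 0.12, 95% confidence interval -0.41 to 0.15, limma adjusted p = 0.461), and the changes differed between the tissues by 0.91 ± 0.18 (limma adjusted p = 0.0108). The values cover the whole gene and do not resolve the floxed part. *Mecp2* thus checked the genotype labels of BAT but not those of iWAT, so the iWAT libraries are called labelled KO and labelled WT, and each iWAT direction rests on these labels.

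**Figure D1:**
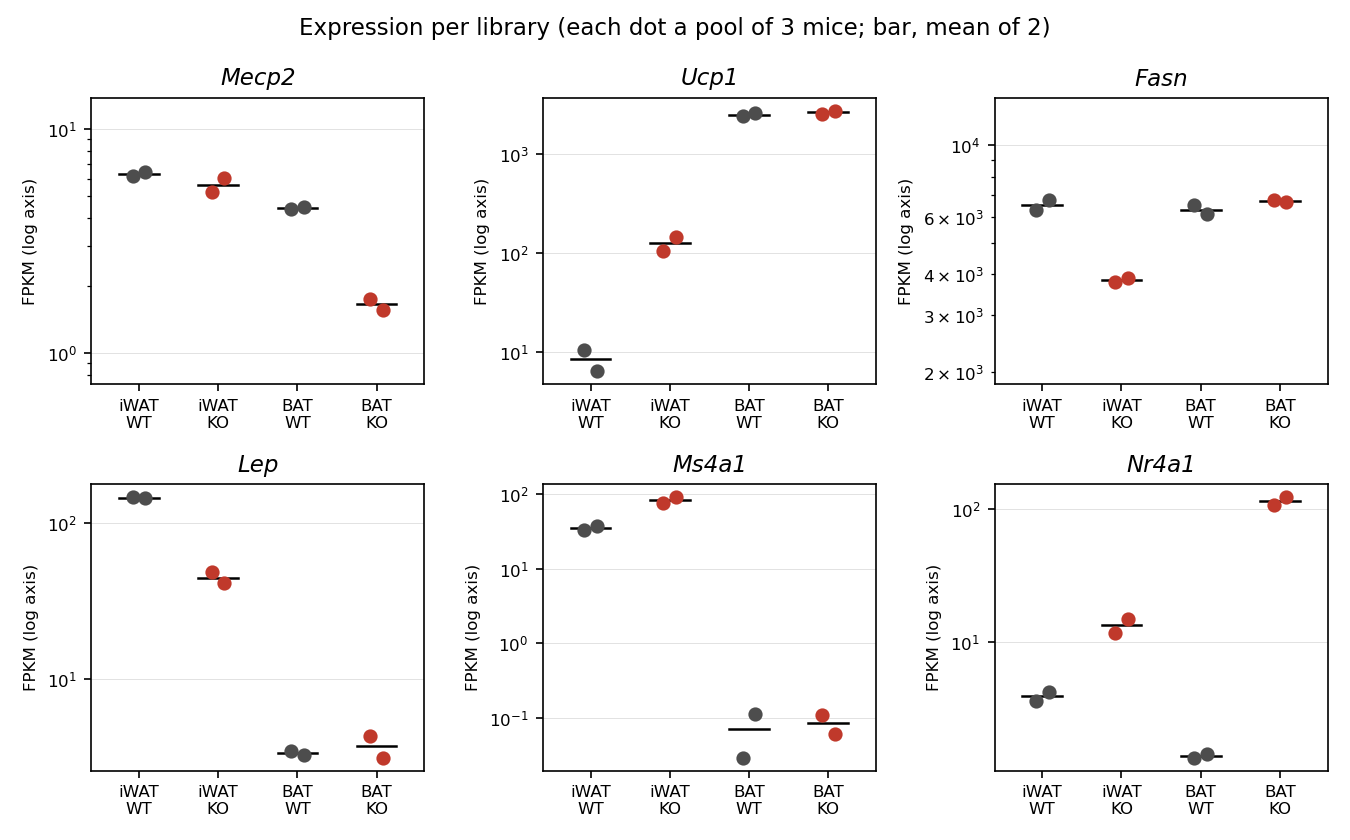
Expression of 6 genes in each library, in FPKM on a log axis, with the libraries grouped by tissue and genotype. Each dot is a pool of 3 mice and each bar the mean of 2 pools. *Mecp2* was lower in both BAT KO libraries, *Ucp1* and *Ms4a1* were higher and *Fasn* and *Lep* lower in both iWAT libraries labelled KO, and *Nr4a1* was higher in both KO libraries of each tissue.

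The comparison in iWAT asked which genes change in white fat with the knockout. Many genes of heat production were higher in the libraries labelled KO. *Ucp1* (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452), the mitochondrial uncoupling protein of thermogenic adipocytes, rose from 8.44 ± 2.86 to 126 ± 28.5 FPKM (3.77 ± 0.19, limma adjusted p = 2.3e-05), against 2497 ± 103 FPKM in BAT WT. *Elovl3*, a fatty acid elongase induced in active brown fat, rose from 3.93 ± 0.497 to 18.6 ± 3.12 FPKM. *Fabp3*, a fatty acid carrier, rose from 1.47 ± 0.302 to 31.8 ± 13.7 FPKM. *Ppargc1a*, a coactivator of mitochondrial genes, rose from 4.26 ± 0.444 to 6.29 ± 0.315 FPKM. Of 26 measured thermogenic genes, 17 rose, 2 fell and 7 did not pass the threshold (17 rose and 3 fell adjusted over the list alone), with a median change of 0.60, or 0.924 with scaling on the adipocyte identity list. The 2 that fell, chosen after their values were seen, were *Cidec* (1876 ± 99.5 to 1197 ± 102 FPKM) and *Ckb* (25.1 ± 0.399 to 17.3 ± 0.695 FPKM). The list as a whole took 0.292% ± 0.0176 of the reads in WT and 0.287% ± 0.000974 in KO, so its share of reads did not rise. That share weighs members by level, and it holds the fall of *Cidec* (1876 to 1197 FPKM) beside the rise of *Ucp1* (8.44 to 126 FPKM). It therefore does not describe the members that rose. The camera adjusted p of the list was 6.89e-05, and adjusted p = 0.303 with an estimated correlation. In the list of fatty acid oxidation, 17 of 30 genes rose, 1 fell and 12 did not pass (19 and 1 adjusted over the list alone; median 0.32, or 0.646 with that scaling; camera adjusted p = 1.03e-06, adjusted p = 0.303 with an estimated correlation). Its members with the smallest adjusted p were *Fabp3* and *Pdk4*, a kinase that inhibits pyruvate dehydrogenase, which rose from 86.4 ± 8.76 to 382 ± 32.4 FPKM. In the same libraries, genes of B and plasma cells took 0.733% ± 0.0344 of the reads, against 0.341% ± 0.0362 in the libraries labelled WT. Skeletal muscle genes took 0.0842% ± 0.0302, against 0.0255% ± 0.0131. The spans of *Fabp3* and *Elovl3* overlap those of other expressed genes (*Zcchc17*, *Gm10570* and *Pitx3*). Some of their reads may belong to these, and overlap of exons was not examined.

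Genes of fat synthesis and of the white adipocyte were lower in the iWAT libraries labelled KO, in which the B and plasma cell share stood at 0.733% of the reads. *Fasn* (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547), the fatty acid synthase, fell from 6539 ± 335 to 3833 ± 76.3 FPKM (-0.77 ± 0.07, limma adjusted p = 0.000246). *Acly*, which makes cytosolic acetyl-CoA from citrate, fell from 1748 ± 4.13 to 839 ± 6.28 FPKM. *Acss2*, which makes it from acetate, fell from 342 ± 2.09 to 183 ± 0.529 FPKM. Of 30 genes of fatty acid and triglyceride synthesis, 27 fell, 2 rose and 1 did not pass (28 and 2 adjusted over the list alone; median -0.68, or -0.336 with scaling on the adipocyte identity list; camera adjusted p = 7.04e-28). The adjusted p of this list was 0.128 with an estimated correlation. *Lep* (ENSMUSG00000059201, chromosome 6, 29060220 to 29073877), the gene of the adipocyte hormone leptin, fell from 146 ± 1.39 to 44.8 ± 5.01 FPKM (-1.69 ± 0.12, limma adjusted p = 9.87e-05). *Npr3*, a clearance receptor of natriuretic peptides, fell from 44.1 ± 2.34 to 14.5 ± 1.34 FPKM. Of 18 white adipocyte genes, 8 fell and 10 did not pass (11 fell and 1 rose adjusted over the list alone; median -0.41, or -0.083 with that scaling; camera adjusted p = 9.36e-09, adjusted p = 0.228 with an estimated correlation). In the list of adipogenesis and adipocyte identity, 19 of 29 genes fell and 10 did not pass (22 fell adjusted over the list alone; median -0.41, or -0.066 with that scaling; camera adjusted p = 6.02e-16, adjusted p = 0.148 with an estimated correlation). The scaling uses this list, so the value of -0.066 is near 0 by construction and is no check of the list. Its leading members were *Slc2a4*, the insulin-responsive glucose transporter (223 ± 8.9 to 125 ± 3.31 FPKM), and *Cebpa*, a transcription factor of adipogenesis (515 ± 5.04 to 314 ± 0.0828 FPKM). *Pparg* fell by 0.41 ± 0.07 (limma adjusted p = 0.00261). *Adipoq*, the gene of adiponectin, fell by 0.27 ± 0.09 (limma adjusted p = 0.0459). *Adipoq* was at 0.07 with scaling on the adipocyte identity list, where it did not pass (limma adjusted p = 0.325).

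Other metabolic lists were lower in the iWAT libraries labelled KO relative to other genes, and each of these medians turned positive when libraries were scaled on the adipocyte identity list. That scaling raised the median change of all iWAT genes as well, from 0.116 to 0.413. Of 24 lipolysis genes, 10 fell and 4 rose (12 and 4 adjusted over the list alone; median -0.20, or 0.133 with that scaling; camera adjusted p = 3.69e-05, adjusted p = 0.303 with an estimated correlation). They included *Plin1* and *Plin4*, coat proteins of the lipid droplet, with *Plin1* at 1607 ± 29.4 and 1061 ± 53.8 FPKM and *Plin4* at 484 ± 13.5 and 291 ± 27.2 FPKM. Of 26 genes of glycolysis and glucose uptake, 11 fell and 2 rose (13 and 3 adjusted over the list alone; median -0.16, or 0.181 with that scaling; camera adjusted p = 5.89e-05, adjusted p = 0.148 with an estimated correlation). *Pdk4* rose and *Slc2a4* fell in this list. Of 22 genes of cholesterol synthesis, 9 fell (9 fell and 1 rose adjusted over the list alone; median -0.21, or 0.111 with that scaling; camera adjusted p = 5.95e-06, adjusted p = 0.148 with an estimated correlation), among them *Mvk* (24.2 ± 1.15 to 14.0 ± 0.298 FPKM) and *Lss* (28.2 ± 0.35 to 18.9 ± 0.503 FPKM). Of 29 genes of insulin, leptin and adrenergic receptors and hormones, 11 fell and 4 rose (13 and 4 adjusted over the list alone; median -0.18, or 0.151 with that scaling; camera adjusted p = 5.03e-06, adjusted p = 0.148 with an estimated correlation). *Lep* and *Angptl8*, a secreted regulator of lipoprotein lipase (35.9 ± 0.426 to 19.9 ± 1.63 FPKM), led it.

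Markers of lymphoid cells and of skeletal muscle were higher in the iWAT libraries labelled KO. Of 30 genes of B and plasma cells, 28 rose and 2 did not pass (28 adjusted over the list alone; median 1.02, or 1.364 with scaling on the adipocyte identity list; camera adjusted p = 4e-13, adjusted p = 0.148 with an estimated correlation). *Ms4a1*, the B cell marker CD20, rose from 35.5 ± 2.78 to 83.2 ± 10.4 FPKM. *Mzb1*, a chaperone of antibody secretion, rose from 18.0 ± 2.73 to 52.0 ± 2.83 FPKM. Among the genes with the largest rise were immunoglobulin genes whose reads similar copies can share. *Ighg2b* was at 14.0 ± 0.0453 and 89.6 ± 62.6 FPKM, *Igkv15-103* at 5.36 ± 2.69 and 33.3 ± 20.1 FPKM, and *Igkv1-135* at 10.5 ± 0.609 and 55.4 ± 14.8 FPKM. *Ighd2-4* was at 0 FPKM in both libraries labelled WT and rested on 1 and 3 reads in those labelled KO. *Ighd3-2* rested on 0 and 1 reads against 3 and 3, so both are uncertain. *Slpi*, a secreted protease inhibitor, rose from 43.9 ± 1.96 to 281 ± 45 FPKM. Of 28 T and natural killer cell genes, 7 rose (8 adjusted over the list alone; median 0.45, or 0.791 with that scaling; camera adjusted p = 0.0027, adjusted p = 0.5 with an estimated correlation), with *Cd2* at 31.6 ± 1.62 and 54.1 ± 3.85 FPKM and *Klrd1* at 16.4 ± 0.192 and 26.7 ± 3.44 FPKM. Of 24 skeletal muscle genes, 9 rose (13 adjusted over the list alone; median 1.53, or 1.691 with that scaling; camera adjusted p = 0.00172, adjusted p = 0.5 with an estimated correlation). *Eno3* rose from 25.9 ± 6.37 to 47.9 ± 8.17 FPKM and *Des* from 19.2 ± 2.01 to 33.2 ± 1.98 FPKM.

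Beside this rise in lymphoid genes, 18 of 31 cell cycle genes rose in iWAT (25 adjusted over the list alone; median 0.56, or 0.846 with scaling on the adipocyte identity list; camera adjusted p = 4.07e-06, adjusted p = 0.303 with an estimated correlation). The mitotic kinase gene *Bub1* was at 1.10 ± 0.166 and 3.14 ± 0.517 FPKM, and *Pcna*, the sliding clamp of DNA replication, at 65.8 ± 2.18 and 84.1 ± 1.72 FPKM. Ribosomal protein genes rose in 42 of 44 cases (42 adjusted over the list alone; median 0.49, or 0.828 with that scaling; camera adjusted p = 1.87e-20, adjusted p = 0.148 with an estimated correlation). *Rpl5* was at 427 ± 13.8 and 647 ± 12.9 FPKM and *Rps4x* at 600 ± 0.257 and 871 ± 15.4 FPKM. Ribosomal protein genes have many processed copies that can share their reads. Of 29 immediate early and stress genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.29, or 0.566 with that scaling; camera adjusted p = 0.013, adjusted p = 0.481 with an estimated correlation). These included *Nr4a1*, a nuclear receptor induced within an hour of many stimuli (3.90 ± 0.432 to 13.3 ± 2.32 FPKM), and *Gadd45g* (21.8 ± 3.01 to 47.4 ± 1.4 FPKM).

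Genes of the matrix, of vessels and of the daily clock were lower in the iWAT libraries labelled KO. Of 31 extracellular matrix genes, 15 fell and 2 rose (15 and 2 adjusted over the list alone; median -0.30, camera adjusted p = 4.51e-09, adjusted p = 0.303 with an estimated correlation). The basement membrane collagen genes *Col15a1* (158 ± 4.38 to 60.8 ± 4.05 FPKM) and *Col4a2* (187 ± 7.88 to 117 ± 0.17 FPKM) fell. Of 24 endothelial and vascular genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.32, camera adjusted p = 1.49e-06, adjusted p = 0.415 with an estimated correlation), with *Gpihbp1* at 73.7 ± 5.22 and 46.5 ± 2.6 FPKM and *Cspg4* at 17.4 ± 0.549 and 10.5 ± 0.578 FPKM. Of 22 fibroblast and preadipocyte genes, 4 fell and 2 rose, also adjusted over the list alone (median -0.11, camera adjusted p = 0.00778, adjusted p = 0.5 with an estimated correlation). In it, *Gsn* fell from 4713 ± 31.3 to 2667 ± 309 FPKM and *Ly6a* rose from 150 ± 9.88 to 197 ± 18 FPKM. Of 13 nerve and Schwann cell genes, 3 fell and 2 rose, also adjusted over the list alone (median -0.09, camera adjusted p = 0.013, adjusted p = 0.457 with an estimated correlation), with *Pmp22* at 128 ± 2.24 and 68.5 ± 4.28 FPKM and *Scn7a* at 20.5 ± 0.5 and 12.4 ± 0.812 FPKM. With scaling on the adipocyte identity list, the medians were 0.041 for the matrix, 0.0 for vessels, 0.199 for fibroblasts, 0.031 for nerve and -0.076 for the clock genes below. Of 20 clock genes, 11 fell (12 fell and 1 rose adjusted over the list alone; median -0.40, camera adjusted p = 1.27e-08, adjusted p = 0.128 with an estimated correlation), among them *Nr1d1* (92.6 ± 3.4 to 54.7 ± 2.04 FPKM) and *Dbp* (58.7 ± 3.54 to 31.8 ± 1.42 FPKM). The arm of *Per*, *Nr1d* and *Dbp* genes had a median of -0.54 (7 of 9 genes called), against 0.31 for the arm of *Arntl* and *Clock* (0 of 2 called). Further genes with the largest fall were *Nnat*, an imprinted proteolipid gene (456 ± 11.4 to 139 ± 20.2 FPKM), the fructose transporter gene *Slc2a5* (38.4 ± 0.899 to 14.0 ± 0.438 FPKM), the albumin gene *Alb* (63.7 ± 6.86 to 24.0 ± 3.35 FPKM) and *Cachd1* (18.9 ± 0.144 to 6.73 ± 0.0695 FPKM). *Dmkn*, a gene of the epidermis, also fell (11 ± 9.98 to 1.94 ± 0.437 FPKM), but did not pass when the first library labelled WT was left out (-0.76). The first library labelled WT held genes of the epidermis that its partner lacked, such as *Krt5* (9.71 against 0 FPKM), a gene chosen after its values were seen. The spans of *Nnat*, *Cebpa*, *Acss2*, *Plin4*, *Des*, *Col4a2*, *Nr1d1*, *Dbp*, *Rpl5* and *Angptl8* overlap those of other expressed genes. Some of their reads may belong to these, and overlap of exons was not examined.

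In all, limma called 3507 of 13347 genes in iWAT, of which 2448 rose (69.8%) and 1059 fell, around a median change of all genes of 0.116. In the simulations of this fit, 12.5% of the iWAT calls were false, more than the adjusted p threshold of 0.05 allows. The fit shares 1 spread per gene between the tissues, and iWAT pools varied more (chi-square per gene 7.92 and 5.82, against 1.75 and 1.72 in BAT). The iWAT adjusted p-values are therefore likely too small. The share that rose was 56.3% of 2981 genes with median-ratio scaling, 45.4% of 3543 with quantile normalization, where the median of all genes was -0.005, and 96.6% of 8442 with scaling on the adipocyte identity list, where that median was 0.413. The count was 1735 without the first library labelled WT, which holds the epidermal genes, 1596 without the second labelled KO, 1711 in a fit to iWAT alone, and 231 with an added fold threshold of 1 on the log2 scale.

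The comparison in BAT asked which genes change in brown fat. Immediate early genes, which respond within minutes to hormones, nerve activity and stress, were higher in the KO libraries. *Nr4a1* (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795) rose from 1.39 ± 0.056 to 115 ± 10.9 FPKM, an 82.9-fold difference in level (5.6 ± 0.13, limma adjusted p = 6.66e-08). *Egr1* rose from 1.42 ± 0.217 to 22.7 ± 0.0537 FPKM (3.30 ± 0.13, limma adjusted p = 1.94e-06). So did *Dusp1* from 17.8 ± 0.0954 to 97.0 ± 4.42 FPKM and *Fos* from 2.96 ± 0.0946 to 17.5 ± 3 FPKM. Of 29 immediate early and stress genes, 20 rose, 1 fell and 8 did not pass (20 and 3 adjusted over the list alone; median 0.85, camera adjusted p = 8.68e-23, adjusted p = 0.292 with an estimated correlation). The member that fell was *Nr4a3*, a relative of *Nr4a1*, which went from 5.25 ± 0.269 to 1.13 ± 0.338 FPKM (-1.56 ± 0.18, limma adjusted p = 0.00173). Other genes with the largest rise were the kinase gene *Sik1* (6.70 ± 0.415 to 35.9 ± 0.873 FPKM), *Ier3* (3.59 ± 0.802 to 17.1 ± 1.48 FPKM), *Gem* (0.673 ± 0.0156 to 4.90 ± 0.0347 FPKM) and *Irs2*, an adaptor of the insulin receptor (4.13 ± 0.209 to 16.7 ± 0.416 FPKM). Erythroid genes took 0.0916% ± 0.00381 of the reads in these KO libraries, against 0.0551% ± 0.00925 in WT.

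Other BAT changes were smaller, and none of the list calls among them held with an estimated correlation. *Ucp1*, *Ppargc1a*, *Adipoq*, *Lep* and *Fasn* did not pass the threshold there. *Ucp1* was at 2497 ± 103 and 2629 ± 128 FPKM (0.07 ± 0.19, limma adjusted p = 0.884), *Ppargc1a* at 23.2 ± 1.03 and 19.5 ± 0.723 FPKM and *Adipoq* at 682 ± 24.6 and 694 ± 33.2 FPKM. *Lep* was at 3.34 ± 0.142 and 3.69 ± 0.818 FPKM and *Fasn* at 6329 ± 279 and 6744 ± 61.3 FPKM. *Pparg* rose by 0.32 ± 0.07 (limma adjusted p = 0.0211). Of 26 thermogenic genes, 4 rose and 1 fell (4 and 2 adjusted over the list alone; median 0.11, camera adjusted p = 0.189). Of 30 fatty acid oxidation genes, 7 rose and 2 fell (8 and 4 adjusted over the list alone; median 0.15, camera adjusted p = 0.000164, adjusted p = 0.937 with an estimated correlation). *Pdk4* rose from 1540 ± 5.18 to 2244 ± 67 FPKM, while *Ehhadh*, an enzyme of peroxisomal oxidation, fell from 107 ± 0.556 to 79.0 ± 2.34 FPKM. Of 26 genes of glycolysis and glucose uptake, 3 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.02, or 0.076 with scaling on the adipocyte identity list and 0.012 with quantile normalization; camera adjusted p = 0.0237, adjusted p = 0.937 with an estimated correlation), and *Irs2* and *Pdk4*, which are regulators and not enzymes of glycolysis, led them. Mitochondrially encoded genes were higher as a list (median 0.22, or 0.0 with quantile normalization; camera adjusted p = 0.0142, adjusted p = 0.937 with an estimated correlation), although 0 of 13 passed by limma, also adjusted over the list alone. They took 19.5% ± 0.307 of the reads in KO and 17% ± 0.226 in WT. The members with the smallest p were *mt-Nd4* (0.30 ± 0.11, limma adjusted p = 0.145) and *mt-Nd6* (0.34 ± 0.15, limma adjusted p = 0.214).

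Red cell genes were higher in BAT KO. Of 8 erythroid genes, 4 rose, also adjusted over the list alone (median 0.60, camera adjusted p = 0.000164, adjusted p = 0.386 with an estimated correlation), among them the near-identical copies *Hba-a1* (137 ± 8.74 to 252 ± 11.8 FPKM) and *Hba-a2* (112 ± 24.2 to 214 ± 6.76 FPKM). Of 31 extracellular matrix genes, 7 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.16, camera adjusted p = 0.0123, adjusted p = 0.937 with an estimated correlation), with *Col15a1* at 19.6 ± 0.0172 and 10.7 ± 1.83 FPKM and *Col6a3* at 11.8 ± 0.985 and 6.98 ± 0.481 FPKM. Of 44 ribosomal protein genes, 4 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.13, or -0.077 with scaling on the adipocyte identity list and -0.08 with median-ratio scaling; camera adjusted p = 7.76e-05, adjusted p = 0.937 with an estimated correlation). *Rpl32* was at 111 ± 13.7 and 86.1 ± 0.915 FPKM, and *Rpl24*, whose reads copies can share, rested on 3 and 0 reads in WT and 8 and 8 in KO. Of 13 nerve and Schwann cell genes, 1 rose and 1 fell (2 and 1 adjusted over the list alone; median 0.28, camera adjusted p = 0.027, adjusted p = 0.937 with an estimated correlation), namely *Mbp* (20.8 ± 1.95 to 28.4 ± 0.26 FPKM) and *Pmp22* (57.2 ± 5.26 to 41.7 ± 0.506 FPKM). The genes with the largest fall, beside *Nr4a3* and *Mecp2*, were the secretin receptor gene *Sctr* (3.37 ± 0.284 to 0.861 ± 0.113 FPKM), *Eci3* (8.83 ± 0.17 to 3.27 ± 0.431 FPKM), *Tceal8* (8.29 ± 0.781 to 3.29 ± 0.74 FPKM), the monocarboxylate transporter gene *Slc16a7* (6.75 ± 0.621 to 2.73 ± 0.402 FPKM), *Desi1* (13.7 ± 2.21 to 6.13 ± 0.485 FPKM) and *Tmem45b* (90.0 ± 2.77 to 44.3 ± 5.27 FPKM). The spans of *Dusp1*, *Irs2*, *Desi1*, *mt-Nd4* and *mt-Nd6* overlap those of other expressed genes. Some of their reads may belong to these, and overlap of exons was not examined.

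**Figure D2:**
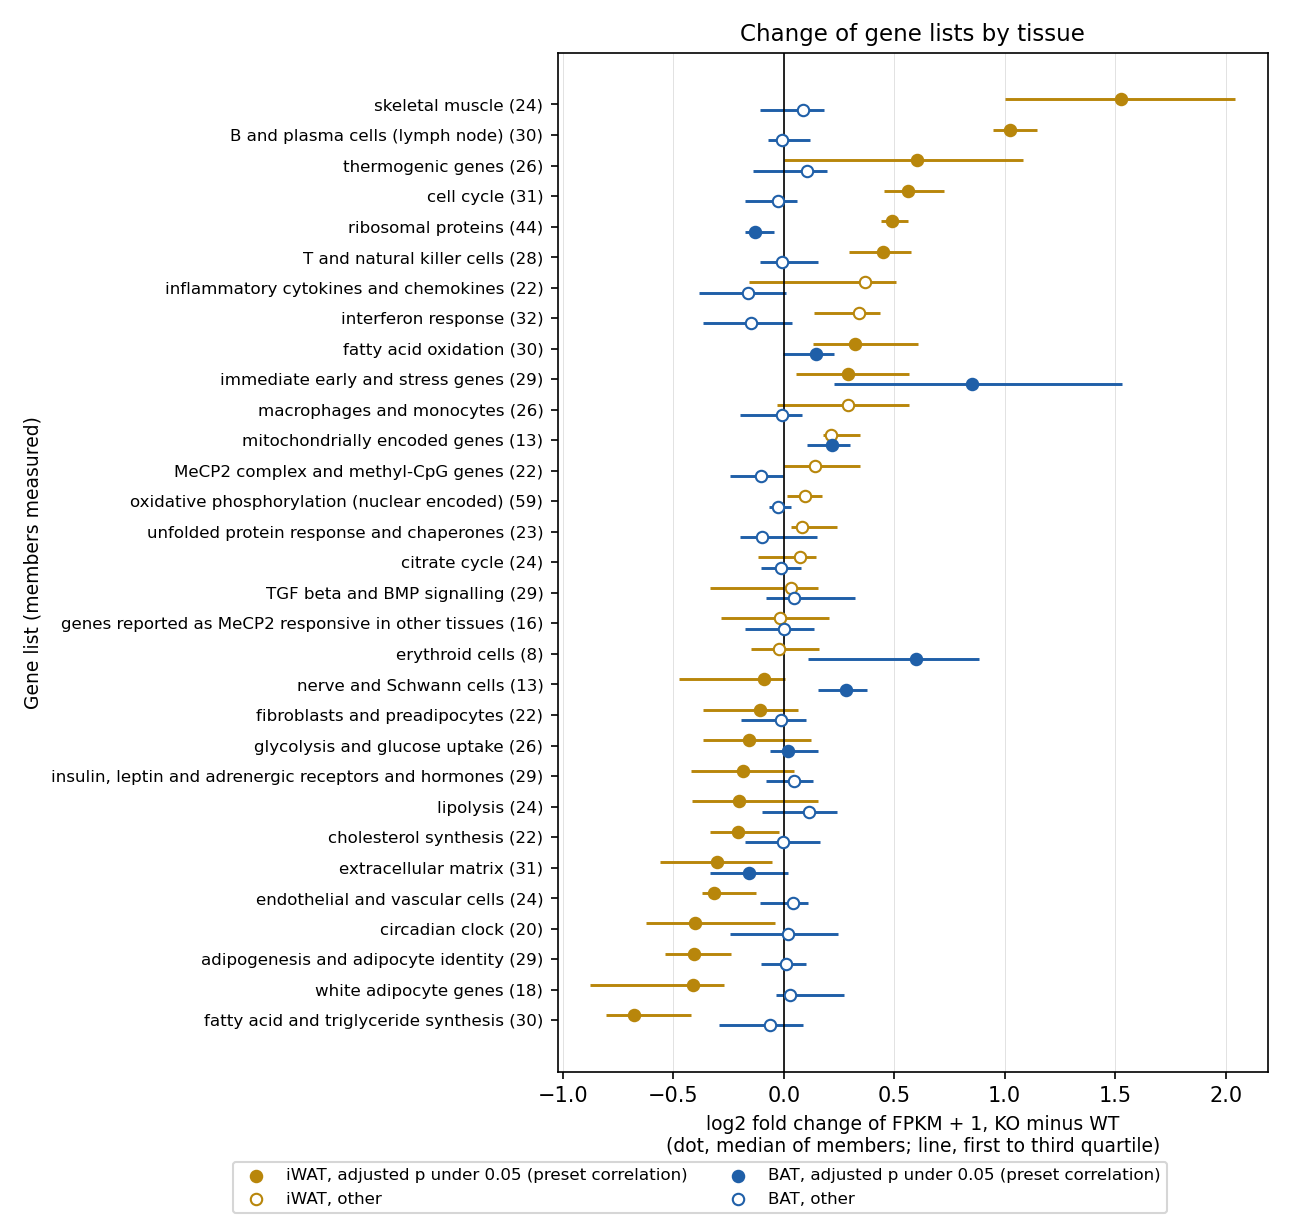
Change of 31 gene lists in iWAT and in BAT, as log2 difference of FPKM + 1 between KO and WT. Dots are medians of the measured members, lines run from the first to the third quartile, filled dots mark lists with a camera adjusted p under 0.05 at the preset correlation, and no list kept that with an estimated correlation. Lists of muscle, B cell and thermogenic genes lie to the right in iWAT (medians 1.53, 1.02 and 0.60) and fat synthesis to the left (-0.68), while in BAT immediate early genes lie farthest right (0.85). With scaling on the adipocyte identity list, the iWAT medians of lipolysis, glycolysis, cholesterol synthesis, receptors, matrix, fibroblasts and nerve lie above 0, and with quantile normalization the BAT median of mitochondrially encoded genes lies at 0.0.

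In all, limma called 852 genes in BAT, of which 397 rose (46.6%) and 455 fell. The share that rose was 62.2% of 905 genes with median-ratio scaling, 58.9% of 560 with quantile normalization, 60% of 861 without mitochondrially encoded genes and 66.4% of 657 with scaling on the adipocyte identity list, so no direction is given to the BAT calls as a whole. The count fell to 155 without the second WT library, 171 without the first, 174 without the first KO library and 183 without the second, and it was 425 in a fit to BAT alone, 327 with no filter on low values and 61 with the fold threshold.

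The genotype changes of the tissues were then compared with each other. *Nr4a1* rose in both tissues, by 4.06 ± 0.18 less in iWAT (limma adjusted p = 3.17e-05). *Dusp1* differed by -2.04 ± 0.12 (iWAT minus BAT). *Dgat2*, which makes triglycerides, was at 2416 ± 3.75 FPKM in iWAT WT and 1260 ± 28.7 FPKM in iWAT labelled KO, against 1800 ± 21.3 and 2555 ± 86.5 FPKM in BAT, a difference of -1.44 ± 0.08 (limma adjusted p = 6.42e-05). The clock repressor gene *Bhlhe40* was at 58.3 ± 2.17 and 37.5 ± 0.966 FPKM in iWAT and at 36.3 ± 0.203 and 78.4 ± 2.34 FPKM in BAT (-1.71 ± 0.09). *Zfp36l2*, which binds messenger RNA, was at 55.3 ± 2.42 and 68.1 ± 1.33 FPKM in iWAT and at 31.6 ± 0.0821 and 106 ± 1.52 FPKM in BAT (-1.42 ± 0.08). *Slpi* differed by 2.93 ± 0.19. Of the 32 lists, 23 differed between the tissues by camera, 9 with the higher change in iWAT and 14 with the lower, and 0 with an estimated correlation. The changes of thermogenic (median difference 0.59), B and plasma cell (1.02), muscle (1.29) and ribosomal protein genes (0.61) were higher in iWAT, and those of fat synthesis (-0.54), white adipocyte (-0.65), clock (-0.45) and immediate early genes (-0.51) were lower. With scaling on the adipocyte identity list these medians were, in the same order, 0.806, 1.328, 1.486, 0.891, -0.253, -0.363, -0.174 and -0.239. Immediate early genes were at -1.026 with limma-voom. Limma called 2300 genes for the difference, 1584 higher in iWAT (68.9%) and 716 lower. The share higher was 46.6% of 1908 with median-ratio scaling, 41.2% of 2082 with quantile normalization and 94.4% of 5334 with scaling on the adipocyte identity list. Among called genes, 108 fell in both tissues and 112 rose in both, while 58 fell in iWAT and rose in BAT and 84 rose in iWAT and fell in BAT. Independent calls would give 36.1, 72.8, 31.5 and 83.5 genes, in the same order. No test of these overlaps is given, since the calls of both tissues share 1 estimate of spread per gene. Without 1 library the count for the difference was 1379 (first iWAT labelled WT), 1243 (second iWAT labelled KO), 1122 and 914 (first and second BAT WT) and 904 and 1082 (first and second BAT KO).

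The tissues of the control mice were compared as a check of the tissue labels. *Ucp1* was higher in BAT WT than in iWAT WT by 8.08 ± 0.19 and *Ppargc1a* by 2.2 ± 0.10, while *Lep* was lower by 5.09 ± 0.12 and *Adipoq* by 1.45 ± 0.09, with limma adjusted p-values of 1.85e-09, 4.72e-08, 2.02e-09 and 2.78e-07. *Pparg* was higher by 0.19 ± 0.07 (limma adjusted p = 0.0238), or 0.61 with median-ratio scaling and 0.64 with scaling on the adipocyte identity list. It did not pass when the second iWAT WT library (0.11), the first BAT WT library (0.18) or the second BAT WT library (0.19) was left out. *Fasn* did not pass (-0.05 ± 0.07, limma adjusted p = 0.559), but was at 0.38 with median-ratio scaling and at 0.41 with scaling on the adipocyte identity list. *Mecp2* was at -0.42 ± 0.12 (limma adjusted p = 0.012), with a direction that turned to 0.40 with quantile normalization. Of 59 nuclear genes of oxidative phosphorylation, 56 were higher in BAT and 3 lower, also adjusted over the list alone (median 1.57, camera adjusted p = 9.54e-42, adjusted p = 0.24 with an estimated correlation). Of 30 B and plasma cell genes, 30 were lower in BAT, also adjusted over the list alone (median -5.35, camera adjusted p = 8.02e-10, adjusted p = 0.24 with an estimated correlation). Limma called 10291 genes, of which 2123 were higher in BAT (20.6%) and 8168 lower, around a median of -0.504. The share higher was 42% of 9290 genes with median-ratio scaling, 56.6% of 9526 with quantile normalization and 43.6% of 8897 with scaling on the adipocyte identity list, and 4443 genes were called with the fold threshold.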

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

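The tests of brown fat as the whole source of the thermogenic rise, of dilution, of handling, of the deleted allele and of *Mecp2* reads from other cells were chosen after the results were seen. The tests of brown fat carried over, of the scaling, of the daily clock and of other cells in BAT were written before. The results here stand out because their genotype change differed between iWAT and BAT by the test of the difference itself (limma adjusted p under the threshold for genes, camera at the preset correlation for lists, of which 0 held with an estimated correlation). Values are the iWAT change minus the BAT change on the log2 scale. Of these 71 genes, 40 kept the call under every alternative that gave a value, and the call was lost most often for *Klrd1* and *Ly6a* (14 of 18 alternatives each), *Scn7a* (12), *Tceal8* (11), *Col15a1* (10) and *Pcna* (10). *Alb* reversed in 2 of 18.

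Among genes, the iWAT change lay above the BAT change by 3.69 for *Ucp1*, 3.46 for *Fabp3*, 2.93 for *Slpi*, 1.59 for *Pdk4*, 1.22 for *Elovl3*, 0.71 for *Ppargc1a* and 0.91 for *Mecp2*. For lymphoid and immunoglobulin genes it did so by 3.37 for *Ighd2-4*, 2.57 for *Ighg2b*, 2.36 for *Igkv15-103*, 2.12 for *Igkv1-135*, 1.43 for *Mzb1*, 1.2 for *Ms4a1*, 0.98 for *Cd2* and 0.74 for *Klrd1*. Muscle genes differed by 0.99 for *Des* and 0.92 for *Eno3*, cell cycle genes by 0.98 for *Bub1* and 0.37 for *Pcna*, and ribosomal protein genes by 0.78 for *Rpl32*, 0.67 for *Rps4x* and 0.64 for *Rpl5*. Genes that fell in BAT differed by 1.75 for *Nr4a3*, 1.25 for *Sctr*, 0.99 for *Ehhadh*, 0.94 for *Tmem45b*, 0.91 for *Tceal8*, 0.88 for *Eci3*, 0.87 for *Desi1* and 0.74 for *Slc16a7*, and *Ly6a* differed by 0.35.

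The iWAT change lay below the BAT change by the following log2 values for immediate early genes and others that rose in BAT, namely -4.06 for *Nr4a1*, -2.21 for *Egr1*, -2.04 for *Dusp1*, -1.71 for *Sik1* and *Bhlhe40*, -1.70 for *Ier3*, -1.67 for *Irs2*, -1.65 for *Fos*, -1.42 for *Zfp36l2*, -1.18 for *Gem* and -0.51 for *Gadd45g*. It did so for adipocyte and lipid genes with -1.79 for *Lep*, -1.57 for *Npr3*, -1.44 for *Dgat2*, -1.03 for *Plin4*, -0.86 for *Acly* and *Fasn*, -0.76 for *Slc2a4*, -0.73 for *Pparg*, -0.69 for *Cebpa*, -0.59 for *Acss2*, -0.54 for *Plin1*, -0.79 for *Lss* and -0.52 for *Mvk*. Further differences were -1.69 for *Nnat*, -1.23 for *Cachd1*, -1.0 for *Alb*, -0.47 for *Slc2a5*, -0.73 for *Gsn*, -0.54 for *Col15a1*, -0.32 for *Col4a2*, -0.65 for *Gpihbp1*, -0.62 for *Cspg4*, -0.45 for *Pmp22*, -0.56 for *Scn7a*, -0.52 for *Mbp* and *Nr1d1*, -0.59 for *Dbp*, -1.02 for *Hba-a1* and -1.12 for *Hba-a2*.

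Among lists, the median difference was 1.29 for skeletal muscle, 1.02 for B and plasma cells, 0.65 for the cell cycle, 0.61 for ribosomal proteins, 0.59 for thermogenic genes, 0.42 for T and natural killer cells, 0.40 for the interferon response, 0.30 for the MeCP2 complex and methyl-CpG genes and 0.25 for fatty acid oxidation. With scaling on the adipocyte identity list these were higher, in the same order 1.486, 1.328, 0.88, 0.891, 0.806, 0.703, 0.651, 0.578 and 0.528, and with median-ratio scaling the last 2 were 0.177 and 0.127. For T and natural killer cells the direction of the test against other genes reversed with limma-voom, although the median was 0.586. It was -0.65 for white adipocyte genes, -0.54 for fatty acid and triglyceride synthesis, -0.51 for immediate early and stress genes, -0.50 for erythroid and for nerve and Schwann cells, -0.45 for the circadian clock, -0.41 for adipogenesis and adipocyte identity, -0.35 for endothelial and vascular cells and -0.30 for cholesterol synthesis. With scaling on the adipocyte identity list these came nearer to 0, in the same order -0.363, -0.253, -0.239, -0.236, -0.248, -0.174, -0.121, -0.078 and -0.026, and immediate early genes were at -1.026 with limma-voom. For adipogenesis and adipocyte identity this follows from the scaling, which uses that list. The median difference was also negative for glycolysis and glucose uptake (-0.26, or 0.011 with scaling on the adipocyte identity list), receptors and hormones (-0.23, or 0.001), lipolysis (-0.15, or 0.129), extracellular matrix (-0.10, or 0.193) and TGF beta and BMP signalling (-0.01, or 0.261).

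In the iWAT libraries labelled KO, thermogenic genes rose and fat synthesis genes fell. The authors' scaling as the source of the fall is argued against by a median of fat synthesis genes of -0.74 with median-ratio scaling. Brown fat as the whole source of the thermogenic rise is argued against by 9 of the 16 risen members that BAT KO holds at 5 FPKM or more, which gained more of their BAT level than the highest share of *Ucp1* (5.32%), such as *Elovl3* (14.3%) and *Cox8b* (10.7%), the latter chosen after its values were seen. Skeletal muscle genes also rose in these libraries (median 1.53), and their part in these shares was not tested. Brown fat carried over into the pools stays open for part of the rise. A set of 10 genes nearly absent from iWAT labelled WT rose by a median of 3.33% of their BAT KO level. This is 74.4% of the *Ucp1* share, above the 50% written in advance as the mark of carried-over brown fat, so that test went with carry-over. However, the 10 include *Ucp1* itself and the thermogenic members *Fabp3* (4.82%), *Slc27a2* (5.78%) and *Dio2* (3.53%). Another 4 (*Kng2*, *Lgr6*, *Car14* and *Mfsd2a*, with highest shares of 1.07%, 0.88%, 2.55% and 3.29%) stayed below the lowest share of *Ucp1* (3.63%). The others were *Ptgds* (3.13%) and *Gm10032* (5.05%). *Zic1* of the thermogenic list gained no share (-0.48%, highest 1.06%), but rested on 1 and 0 reads in iWAT labelled KO, against 75 and 104 in BAT KO. These genes, *Ucp1* and *Fabp3* apart, were also chosen after their values were seen. Dilution of adipocyte RNA by lymphoid RNA cannot be told apart as a source of the fall. The median of fat synthesis genes (-0.68) lay below that of 41 other adipocyte genes (-0.37) by -0.30. The 95% bootstrap interval of this difference (-0.42 to -0.09) excludes 0 but reaches past the bound of -0.2 set for dilution. With 2 pools per group, this interval describes the genes of the lists and cannot stand for the spread between pools or mice. A shift in the time of collection stays open too, since the clock arms moved apart in iWAT. The *Arntl* and *Clock* arm was at 0.31 (0 of 2 genes called) and the *Per*, *Nr1d* and *Dbp* arm at -0.54 (7 of 9). No test of such a shift was written for iWAT. An effect of the knockout also stays open, untested apart from the labels.

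In BAT KO, immediate early genes rose. Macrophages or muscle in the KO pools are argued against, since the higher of the medians of these lists was 0.09. A shift in the time of collection cannot be told apart from the genotype, because the *Arntl* and *Clock* arm had a median of -0.24 over 2 genes (0.24 in size) and the arm of *Per*, *Nr1d* and *Dbp* genes 0.03 over 9 genes, between the bounds set in advance, while in iWAT these arms moved apart (0.31 and -0.54), with a sign that rests on the labels. Handling before RNA extraction cannot be told apart either, because the iWAT median of the list was 34.1% of the BAT median (19.7% with quantile normalization and 60.8% with scaling on the adipocyte identity list), between the bounds set for a like rise and for none, and with the iWAT labels turned it would be negative, the value set against handling. A response of BAT to the loss of *Mecp2* stays open, untested apart from these.

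*Mecp2* did not pass the threshold in iWAT labelled KO. A deleted allele that still gives counted reads is argued against, since *Mecp2* in BAT of the same line fell to a KO to WT ratio of 0.37. *Mecp2* reads from cells other than adipocytes cannot be told apart from a partial deletion, because 4 iWAT libraries are fewer than the 6 that a relation with other cells' markers needs. Neither the share of adipocyte RNA in the pools nor the deletion in iWAT is recorded in the files, so a lower effect of the knockout in iWAT stays open as a biological explanation.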

How the results depend on the processing

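Limma-voom on recovered reads, scaling on the adipocyte identity list, and for the gene lists all settings but the other set tests and the replicate block, were chosen after the data were seen. Quantile normalization, the other filters, the smaller pseudocount and the fit without mitochondrially encoded genes were planned for the counts of genes, and single genes were read from the same fits. In iWAT, *Mecp2* stayed short of the threshold in every fit run, with a direction that turned from -0.13 to 0.16 with scaling on the adipocyte identity list, and in BAT its fall stayed past it in every fit run. Of the genes named as called, 42 of 52 in iWAT, 13 of 27 in BAT, 40 of 71 for the tissue difference and 4 of 6 for BAT against iWAT kept their call under every setting that gave a value. Counts of genes that moved by over 1.5 times were these, and the cause was not tested unless the setting names it. In iWAT the count (3507) went to 1711 in a fit to iWAT alone and to 231 with the fold threshold. It went to 8442 with scaling on the adipocyte identity list, which by construction holds falling genes near 0, and to between 1596 and 3446 without 1 library. In BAT (852) it went to 560 with quantile normalization, 327 with no filter, 425 in a fit to BAT alone, 61 with the fold threshold and between 155 and 183 without 1 library. For the tissue difference (2300) it went to 1101 with no filter, 342 with the fold threshold, 5334 with scaling on the adipocyte identity list and between 904 and 2473 without 1 library. For BAT against iWAT in WT (10291) it went to 4443 with the fold threshold. A group left with 1 library was assumed to vary like the other groups.

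By camera, 20, 8, 23 and 17 lists were called in iWAT, BAT, the tissue difference and BAT against iWAT, and 0 with an estimated correlation in each of these 4 comparisons, where the test allows for the correlation within a list. Among the lists it missed was oxidative phosphorylation between the tissues of the control mice, with 56 of 59 genes higher in BAT (camera adjusted p = 0.24 with an estimated correlation). With 2 libraries per group, a miss by that test cannot tell a list without change from a lack of power. Fry called 1 list in BAT and 28 in BAT against iWAT, 15 in iWAT and 16 for the tissue difference, and it does not compare a list with other genes. *Mecp2* in BAT against iWAT in WT (-0.42) was at -0.06 with median-ratio scaling, -0.27 without mitochondrially encoded genes and -0.03 with scaling on the adipocyte identity list, each without the call. It reversed to 0.40 with quantile normalization. Over the libraries left out it lay between -0.44 and -0.39, and the call was lost without the first BAT WT library.

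Other reversals of a result past the threshold in at least 1 of the 2 fits compared were these, with causes not tested. *Adipoq* in iWAT went to 0.07 with scaling on the adipocyte identity list, of which it is a member. *Alb* for the tissue difference went to 0.08 with the smaller pseudocount and 0.60 with limma-voom. *Fasn* in BAT against iWAT went to 0.38 with median-ratio scaling and 0.41 with scaling on the adipocyte identity list. For lists, the direction of the test against other genes reversed in iWAT for oxidative phosphorylation without 1 library (medians between 0.005 and 0.18) and for the citrate cycle with scaling on the adipocyte identity list (0.414). For the tissue difference it reversed for mitochondrially encoded genes with quantile normalization (0.191), the citrate cycle with scaling on the adipocyte identity list (0.355) and T and natural killer cells with limma-voom (0.586). In BAT against iWAT, quantile normalization reversed adipogenesis (-0.387) and fat synthesis (-0.163). Fry gave the direction of the medians, against camera, for adipogenesis (-0.441), fat synthesis (-0.101), lipolysis (-0.429), genes reported as MeCP2 responsive (-0.291), erythroid cells (-0.535) and the circadian clock (-0.057). It also differed from camera in direction for lists that neither test called, namely skeletal muscle, endothelial and epithelial cells there, the citrate cycle in iWAT, in BAT and for the tissue difference, mitochondrially encoded genes for the tissue difference, and adipogenesis, oxidative phosphorylation, epithelial cells and genes reported as MeCP2 responsive in BAT.

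The replicate numbers are shared by the groups, but nothing in the labels pairs the pools. With the replicate block, the counts were 3771 in iWAT, 979 in BAT, 2561 for the tissue difference and 10342 for BAT against iWAT, and 1963 for the tissue difference with the pool as a block. Deviations of same-numbered pools correlated at 0.24 between the iWAT groups and -0.06 between the BAT groups, across genes. DESeq2 and its size factors were not run, although whole reads had been recovered. Median-ratio scaling of FPKM stood in for the size factors, and of the count tests only limma-voom was run on the recovered reads. At 9062560 to 11693476 reads, a gene near 1 FPKM rests on few reads, and a change of 0.5 on the log2 scale was recovered in 20.6% (iWAT) and 24.2% (BAT) of simulated genes. Recovery of single genes was not simulated for changes below 0.5, and the 0.4 shift of ribosomal protein genes was read as a list alone.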

Other observations

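The test of long genes was chosen before its result was seen, and the comparison of paired libraries after the data were seen. Immune lists other than those of lymphocytes did not pass in iWAT by camera. Among 26 macrophage and monocyte genes, 8 rose and 0 fell (9 and 1 adjusted over the list alone; median 0.29, camera adjusted p = 0.213). Of 32 interferon response genes 6 rose and 0 fell (5 and 0; median 0.34, camera adjusted p = 0.0785), and of 22 inflammatory cytokine genes 6 rose and 4 fell (7 and 4; median 0.37, camera adjusted p = 0.994). In the same order, these medians were 0.601, 0.659 and 0.586 with scaling on the adipocyte identity list and 0.17, 0.282 and 0.232 with quantile normalization. Mitochondrial lists did not pass there either. Of 59 nuclear genes of oxidative phosphorylation, 5 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.279). Of 13 mitochondrially encoded genes 2 rose (0 adjusted over the list alone; camera adjusted p = 0.18), and of 24 citrate cycle genes 5 rose and 3 fell (5 and 4; camera adjusted p = 0.537), with a median of 0.07 above 0 (0.414 with scaling on the adipocyte identity list) but a test direction below other genes. Genes of the MeCP2 complex rose in 8 of 22 cases and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.339), and of 16 genes reported as MeCP2 responsive in other tissues, 2 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.107). The unfolded protein response had 7 of 23 genes that rose and 2 that fell, also adjusted over the list alone (camera adjusted p = 0.454). TGF beta and BMP signalling had 3 of 29 that rose and 5 that fell (3 and 6; camera adjusted p = 0.0946), with a median of 0.03 against a mean of -0.02, and a median of 0.307 with scaling on the adipocyte identity list and -0.104 with quantile normalization. Erythroid cells had 0 of 8 that rose and 1 that fell, also adjusted over the list alone (camera adjusted p = 0.235), and neither of the 2 measured epithelial genes passed (camera adjusted p = 0.11).

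In BAT, 24 lists did not pass by camera at the preset correlation, thermogenic genes among them. Fat synthesis genes took a lower share of the reads in BAT KO (11.3% ± 0.109) than in BAT WT (13.7% ± 0.172), a share that weighs members by level. By members, fat synthesis had 4 of 30 genes that rose and 9 that fell (6 and 11 adjusted over the list alone; camera adjusted p = 0.454). In the same order, the values were lipolysis 6 of 24 and 3 (8 and 4; 0.061), and the receptors and hormones 6 of 29 and 5 (6 and 6; 0.258). They were adipogenesis 3 of 29 and 4 (5 and 5; 0.673), white adipocyte genes 1 of 18 and 1 (1 and 1; 0.351) and cholesterol synthesis 2 of 22 and 0 (2 and 0; 0.351). The clock had 3 of 20 genes that rose and 3 that fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.445), the unfolded protein response 2 of 23 and 3 (3 and 8; 0.479), and TGF beta and BMP signalling 3 of 29 and 1 (4 and 2; 0.214). They were for the MeCP2 complex 0 of 22 and 4 (0 and 4; 0.061), MeCP2 responsive genes 2 of 16 and 2 (3 and 3; 0.849), the citrate cycle 1 of 24 and 1 (2 and 2; 0.849), and inflammatory cytokines 1 of 22 and 1 (1 and 2; 0.479). By limma, 1 gene fell and 0 rose among B and plasma cell (camera adjusted p = 0.479), fibroblast (0.849), endothelial (0.351) and cell cycle genes (0.849), with 1, 1, 0 and 0 that fell adjusted over the list alone. No member passed, in either count, among genes of oxidative phosphorylation (camera adjusted p = 0.849), macrophages (0.849), T and natural killer cells (0.588), skeletal muscle (0.673), epithelial cells (0.885) and the interferon response (0.189).

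Between the tissues of the control mice, camera called 17 lists at the preset correlation and 0 of 32 with an estimated correlation. Beside oxidative phosphorylation, the lists higher in BAT were thermogenic genes (22 of 26 higher, median 3.33), citrate cycle (23 of 24, 1.76), fatty acid oxidation (25 of 30, 1.74), mitochondrially encoded genes (13 of 13, 1.67), glycolysis and glucose uptake (18 of 26, 0.57) and fat synthesis, which had a median of -0.10 that was higher only relative to all genes (camera adjusted p = 0.0496) and rose to 0.323 with median-ratio scaling. The direction of its test turned with quantile normalization (median -0.163) and with fry (Down, fry adjusted p = 0.381). Those lower in BAT, beside B and plasma cells, were T and natural killer cells (28 of 28 lower, median -3.83), white adipocyte genes (16 of 18, -3.38), macrophages (26 of 26, -2.74), fibroblasts (19 of 22, -2.34), extracellular matrix (29 of 31, -1.97), interferon response (30 of 32, -1.61), cell cycle (30 of 31, -1.50), ribosomal proteins (44 of 44, -1.40) and inflammatory cytokines (17 of 22, -1.29). These medians moved with the scaling. With quantile normalization they were -0.606 for the cell cycle, -0.678 for inflammatory cytokines, -0.784 for the interferon response, -2.053 for macrophages, -2.654 for white adipocyte genes and -3.015 for T and natural killer cells. With limma-voom these were -2.773, -1.489, -2.005, -3.284, -3.842 and -5.596. With scaling on the adipocyte identity list the median was 0.985 for glycolysis, -0.941 for ribosomal proteins, -1.528 for the matrix and -1.933 for fibroblasts.

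A hypothesis was that loss of MeCP2 raises long genes. Genes spanning at least 100 kb (1543, against 10523 others) were not raised in both tissues, which the hypothesis had been written to require. Their median change was 0.05 against 0.112 in iWAT, which lay lower (camera adjusted p = 0.0336). In BAT it was 0.028 against -0.041, which lay higher (camera adjusted p = 0.00443). The adjusted p was 0.522 in each with an estimated correlation. *Mecp2* fell past the threshold in BAT alone, so the iWAT values cannot test an effect of its loss.

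Libraries of a group differed in some genes, chosen here after their values were seen. The first iWAT library labelled WT held 29 genes at over 8 times the level of its partner. They included the epidermal genes *Lor* (37.6 against 0.211 FPKM), *Krt10* (47.2 against 2.83 FPKM) and *Krt14* (10.9 against 0 FPKM), and *Hsp90aa1* (304 against 11.9 FPKM), *Rpl12* (369 against 29.1 FPKM) and *Gm42418* (103 against 3.64 FPKM). Muscle genes varied between pools, with *Myh4* at 5.90 and 48.7 FPKM and *Myh1* at 14.6 and 0.562 FPKM in the iWAT libraries labelled KO. The list of testis and epididymis genes had no measured member.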
